A study of Homo sapiens with 18 samples.

How the data were processed

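Gene expression was measured in HUVEC on 18 whole-transcript Affymetrix arrays, with 3 arrays in each of 6 groups: untreated cells, cells with IgG beads, and cells with CD63+ or MHC1+ EVs of Jurkat or JinB8 T cells. Per the labels, the co-culture lasted 3 days and 300 ng of total RNA was labelled for each array, and conditioned media were pooled for each donor cell before the EVs were captured. The RNA kit in the sample labels differs from that in the series design, and how well short RNAs were retained is not known. Per the submitters' processing notes, the authors summarised the arrays with RMA in Affymetrix Expression Console; the versions are not given in the sources used here. RMA corrects background, quantile-normalizes the arrays and gives log2 values. The values deposited by the authors are taken as log2 RMA signal, a scale that the table does not state and that was read from their range. Arrays have no read depth, and their number limits the precision.

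The value table held 33297 probe sets. Of these, 12083 had no gene in the platform annotation and 1754 had several symbols, and they were left out of the gene tests. Of the 19460 probe sets with 1 symbol, the one with the highest mean over all 18 arrays was kept for each gene, which left 18395 genes, 788 of which had more than 1 probe set. The symbols of 7 genes were updated through their Entrez numbers. No filter on level was used, and no detection calls were analysed here. XIST and Y-linked genes, 23 in all, were tested but are not named. Groups were taken from the bracketed part of the sample names. No batch or processing date was used here, and the arrays of a group have neighbouring serial numbers, so that a batch effect, if there was any, cannot be told apart from the group.

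A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). Comparisons used its moderated t, two-sided, and a moderated F test for any difference among the 6 groups. P-values were adjusted by Benjamini and Hochberg over the 18395 genes of each comparison, and a gene was called at an adjusted p under 0.05. There were 14 such results: beads against untreated cells, each EV group and the mean of the 4 EV groups against beads, JinB8 against Jurkat EVs within each capture and averaged, CD63+ against MHC1+ EVs within each donor cell and averaged, the interaction of donor cell and capture, and the F test. Gene differences are given with the SE of the model and group levels with the SD. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

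The 24 gene lists were tested in every comparison with camera and its preset correlation of 0.01, adjusted over the lists of a comparison. Each call was tested again with a correlation estimated from the data, and with fry. Members past the threshold were counted over all genes and adjusted over the list alone. List means per array were also compared by exact permutation of the arrays, two-sided, a test chosen after seeing the data. The lists cover interferon-stimulated genes, antigen presentation, NF-kB-driven activation, endothelial identity, angiogenesis and Notch, TGF-beta and mesenchymal transition, G2 and mitosis, G1/S and replication, the unfolded protein response, hypoxia and glycolysis, cholesterol and fatty acid synthesis, p53 targets, oxidative stress and metallothioneins, the CD47 and thrombospondin axis, tetraspanins and vesicle biogenesis, markers of T cells, fibroblasts and smooth muscle, monocytes and epithelium, ribosomal proteins, the respiratory chain, histones, small nucleolar and spliceosomal RNAs, and microRNA precursors.

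The groups, comparisons, tests, lists, other settings to try and the rule for naming genes were fixed before the data were examined. The rule names, among genes called whose groups do not overlap, the 10 largest rises and the 10 largest falls of a comparison. Where fewer than 5 genes pass, it names the 5 with the smallest unadjusted p. It adds up to 4 members of each list with the smallest adjusted p, and a few genes set in advance (among them CD47, THBS1, CD63 and NOS3). The text gives a selection of the genes so named, and the same rule was applied in the 16 arrays. STC1 and the other genes that the rule names in another comparison are given across comparisons for their values.

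Other settings chosen in advance were untreated cells as the control, leaving out the lowest 25% or 50% of genes by mean level, all probe sets tested separately, limma with trend and robust options, quantile normalization of the arrays again, centring on array medians, array weights, only the groups compared, a minimum of 1.5-fold, and leaving out each array in turn. After the data were seen, arrays whose correlation with the others lay under 0.9 were left out (16 arrays), Jurkat MHC1+ replicate 1 was left out as well (15 arrays), the array SD was added as a covariate, and gene lists were compared with untreated cells. The fit and the list test were tried on simulated data with 50 changed genes at each of several fold changes. The simulated noise was independent between genes, with 1 SD per gene for all arrays. In the data, the spread is widened by 2 discordant control arrays and is shared between genes. The shares found and the false calls given next may therefore not hold for the real arrays. Of the genes changed 2-fold, 4% (the interaction) to 50% (JinB8 against Jurkat EVs averaged) were found with the spread of the 18 arrays, with 8% for Jurkat MHC1+ EVs against beads, 20% for JinB8 against Jurkat CD63+ EVs and 44% for the mean of the 4 EV groups against beads. With the spread of the 16 arrays 54% (the interaction) to 100% (JinB8 against Jurkat EVs averaged) were found. A comparison made 0 to 9 false calls with the 18 arrays and 3 to 14 with the 16 (14 for JinB8 MHC1+ EVs against beads and for the captures within JinB8), and none of the genes found went in the wrong direction. A count of 0 genes in the 18 arrays still leaves room for many changes of 2-fold, though their share in the real arrays is not known.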

Results

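Gene expression was measured in human umbilical vein endothelial cells (HUVEC), the cultured lining cells of a vein, on 18 Affymetrix whole-transcript arrays in 6 groups of 3. The untreated group received nothing, and the bead group received beads carrying only immunoglobulin G (IgG). The labels give 3 days for the bead group and no time for the untreated group. The other 4 groups were kept for 3 days with extracellular vesicles (EVs), the membrane particles that cells shed, from a T cell line. The EVs came from Jurkat, a human T cell leukaemia line, or from JinB8, a Jurkat derivative that lacks the cell surface receptor CD47. They had been captured on beads through CD63, a tetraspanin of endosome-derived vesicles, or through MHC class 1 (MHC1), the complex that presents peptides on the cell surface. The design asks what each vesicle subset does to endothelial gene expression and whether CD47 on the donor cell alters it. In the free text, 5 of the 6 JinB8 arrays carry other numbers after the JinB stem, while the bracketed name of each says JinB8, so all 6 were taken as JinB8. All values are on the log2 scale of RMA, and their precision is limited by the number of arrays. Nothing states that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

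The endothelial identity genes (29 measured, among them the junction and receptor genes that mark this cell type) had a mean level of 8.33 to 8.45 in the 4 EV groups. The T cell markers, which would show RNA of the donor cells, lay between 4.15 and 4.37 in these groups. In 2 control arrays the picture was different. Untreated replicate 3 and bead replicate 3 correlated with the remaining arrays at a median Pearson's r of 0.649 and 0.636, whereas no pair among the other 16 arrays correlated below 0.932. The correlation between these 2 arrays was 0.830. Their values were compressed, with an SD over all probe sets of 1.56 and 1.57. The 1840 genes with the highest mean level in the other 16 arrays averaged 6.60 and 6.29 there against 8.98 to 9.65 elsewhere. This ranking left the 2 arrays out, so some of the gap may come from it. Jurkat MHC1+ replicate 1 was intermediate, with an SD of 2.01 and a median r of 0.947. Every comparison was fitted on all 18 arrays as planned before the data were examined. The fits on 16 arrays (without the 2 discordant controls), on 15 arrays (also without Jurkat MHC1+ replicate 1) and on 16 arrays with the array SD as a covariate were chosen after seeing the data.

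**Figure D1:**
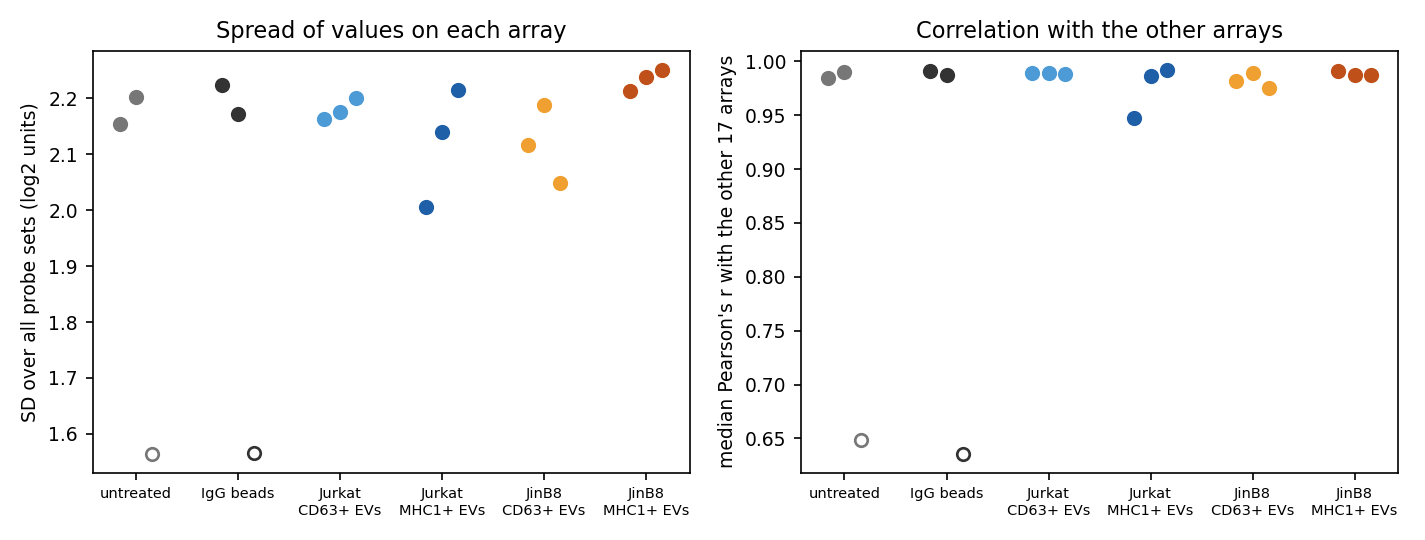
Left, the SD of all probe set values on each array in log2 units; right, each array's median Pearson's r with the other 17 arrays. Each point is 1 array, grouped by treatment; the open points, untreated replicate 3 (SD 1.56, r 0.649) and bead replicate 3 (SD 1.57, r 0.636), lie apart from the filled points of the other 16 arrays.

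The comparison of the 4 EV groups together with the bead control asks what the vesicles share. STC1, which encodes the secreted glycoprotein stanniocalcin 1, rose by 1.27 ± 0.14 (SE, 12 EV arrays against 3 bead arrays; limma adjusted p = 0.0041). Its level was 6.71 ± 0.21 (SD, n = 3) with beads and 6.67 ± 0.25 in untreated cells. It stood at 8.23 ± 0.05 with Jurkat CD63+ EVs, 7.27 ± 0.17 with Jurkat MHC1+ EVs, 8.78 ± 0.06 with JinB8 CD63+ EVs and 7.67 ± 0.17 with JinB8 MHC1+ EVs. With 16 arrays 5 genes rose and 3 fell. Those that rose, besides STC1 at 1.39 ± 0.12 (adjusted p = 0.00012), belong to lipid synthesis or its control. FASN, the fatty acid synthase, rose by 1.04 ± 0.14 (adjusted p = 0.01). DHCR7, the enzyme of the last step of cholesterol synthesis, rose by 1.01 ± 0.13 (adjusted p = 0.01). FADS2, a fatty acid desaturase, rose by 0.82 ± 0.11 (adjusted p = 0.01) and INSIG1, a regulator that restrains the pathway, by 1.32 ± 0.21 (adjusted p = 0.032). Of the genes that fell in the 16 arrays, ASPM, a spindle pole protein, fell by 1.15 ± 0.18 (adjusted p = 0.027), BUB1B, a kinase of the mitotic checkpoint, by 1.04 ± 0.15 (adjusted p = 0.016) and TGFBI, a matrix protein induced by TGF-beta, by 0.66 ± 0.10 (adjusted p = 0.016). The size of these falls depends on leaving out bead replicate 3. In the 18 arrays the differences were -0.49 ± 0.37 for ASPM, -0.70 for BUB1B and -0.20 ± 0.28 for TGFBI, none past the threshold. Without bead replicate 1 they were -0.11, -0.44 and 0.06. In all 18 arrays STC1 was the 1 gene past the threshold, 705 genes had an unadjusted p under 0.05, and FASN was at 1.59 ± 0.29 (adjusted p = 0.52). With each array left out in turn, the rises ranged from 1.04 to 1.91 for FASN and from 1.01 to 3.16 for DHCR7. They ranged from 0.82 to 2.91 for FADS2 and from 1.32 to 2.22 for INSIG1. The count of 1 fell to 0 without bead replicate 1 or bead replicate 2, with limma's trend and robust options, and after quantile normalization of the arrays again. With 15 arrays 15 genes rose and 13 fell.

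**Figure D2:**
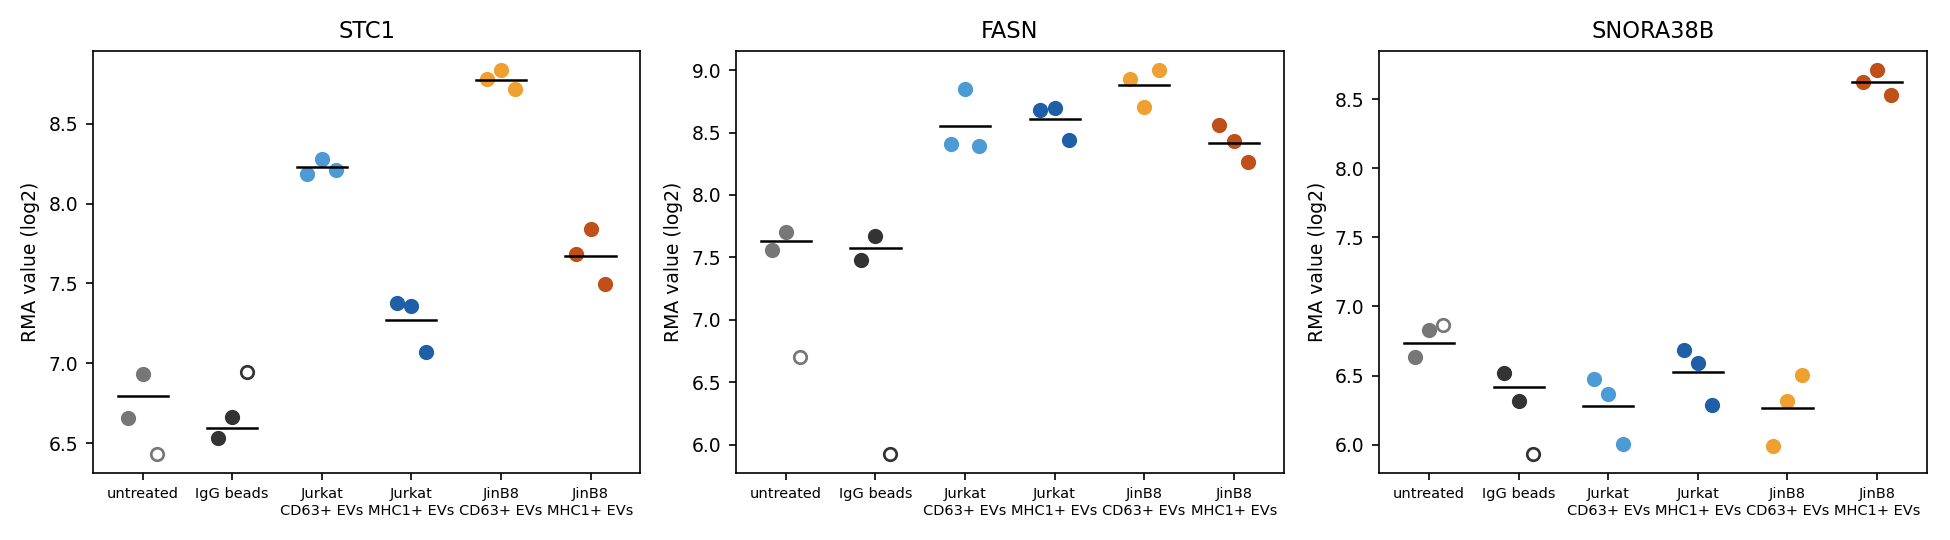
RMA values (log2) of STC1, FASN and SNORA38B on each array, by treatment group; filled points are the 16 concordant arrays, open points the 2 discordant controls, and the black line is the mean of the filled points. STC1 is 8.78 with JinB8 CD63+ EVs and 8.23 with Jurkat CD63+ EVs against 6.60 in the filled bead arrays, and SNORA38B is 8.62 with JinB8 MHC1+ EVs against 6.42.

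The genes of cholesterol and fatty acid synthesis were higher in the EV groups as a set. The median of the 23 measured members was 1.59 above the beads in the 18 arrays, with all 23 positive; 0 passed over all genes and 17 rose when adjusted over the list alone. Camera called the list (adjusted p = 3.3e-20), and the call was lost with an estimated correlation (adjusted p = 0.20 with an estimated correlation). Part of this size came from bead replicate 3, where the mean of the list was 5.64 against 7.81 and 7.72 in the other bead arrays. In the 16 arrays the median was 0.74, 4 members rose over all genes and 19 adjusted over the list alone, and the list was called with either correlation (adjusted p = 0.017 with an estimated correlation). SCD, the stearoyl-CoA desaturase, was at 1.03 ± 0.19 there (adjusted p = 0.12). Against untreated cells the median in the 16 arrays was 0.81 (adjusted p = 0.0061 with an estimated correlation). List means differed by 0.79 between the 12 EV arrays and the 4 concordant control arrays (exact permutation p = 0.0022, two-sided; adjusted p = 0.026 over the 24 lists). Against the 2 concordant bead arrays alone, p was 0.033 (adjusted p = 0.26; 0.011 is the smallest that 91 splits can give). The EV arrays lay between 7.58 and 8.89 and the control arrays between 7.57 and 7.81, and the EV array within the control range was Jurkat MHC1+ replicate 1, the array of intermediate quality.

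The G2 and mitosis genes, which peak as cells divide, were lower in the EV groups. Their median was -0.23 in the 18 arrays (camera adjusted p = 0.0029; adjusted p = 0.49 with an estimated correlation), with 0 of 30 members past the threshold over all genes or adjusted over the list alone. In the 16 arrays the median was -0.63 with all 30 members negative, 2 fell over all genes and 21 adjusted over the list alone, and the list was called with an estimated correlation (adjusted p = 0.017). MKI67, the proliferation marker Ki-67, was at -0.89 ± 0.16 (adjusted p = 0.081) in the 16 arrays. List means differed by -0.62 between the 12 EV arrays and the 4 concordant controls (exact permutation p = 0.0011, two-sided; adjusted p = 0.026 over the 24 lists), and p was 0.022 (adjusted p = 0.26) against the 2 concordant bead arrays alone. The EV arrays spanned 5.37 to 6.17 and the controls 6.15 to 6.63. The fall was not even between the EV groups. The mean of the list was 6.06 with Jurkat CD63+ EVs, 5.61 with Jurkat MHC1+ EVs, 5.61 with JinB8 CD63+ EVs and 5.72 with JinB8 MHC1+ EVs. It was 6.33 in the concordant untreated arrays and 6.39 in the concordant bead arrays. Without bead replicate 1, whose list mean was the highest of all arrays, the median over the remaining 17 arrays was 0.08. The bead group then held replicate 2, with a list mean of 6.15, and the discordant replicate 3, with 5.14.

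**Figure D3:**
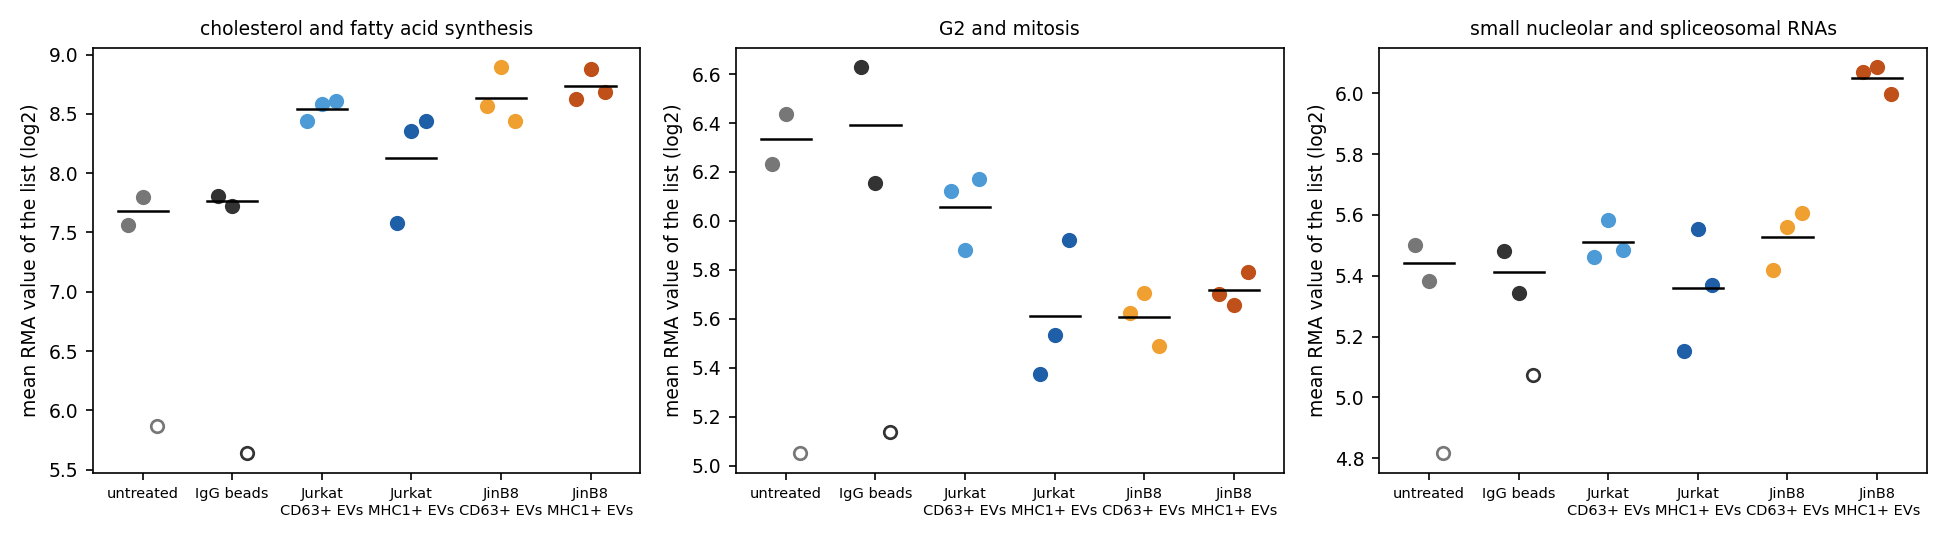
Mean RMA value (log2) of the members of 3 gene lists on each array, by treatment group; filled points are the 16 concordant arrays, open points the 2 discordant controls, and the black line is the mean of the filled points. The cholesterol and fatty acid list is 7.57 to 7.81 in the filled controls, the G2 and mitosis list 6.15 to 6.63, and the small nucleolar RNA list is highest with JinB8 MHC1+ EVs at 6.05.

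Other lists moved with bead replicate 3, the discordant array of the bead group. The type I interferon-stimulated genes, the antiviral response genes, had a median of 0.79 against the beads in the 18 arrays (camera adjusted p = 4.4e-05; adjusted p = 0.49 with an estimated correlation) and a median of -0.29 in the 16 arrays (adjusted p = 0.15 with an estimated correlation). The endothelial identity list went from 0.78 (adjusted p = 0.40 with an estimated correlation) to -0.07, the ribosomal proteins from 0.80 (adjusted p = 0.40 with an estimated correlation) to 0.10, and the T cell markers from -0.31 (adjusted p = 0.49 with an estimated correlation) to 0.05. The TGF-beta and mesenchymal transition list went from 0.50 (adjusted p = 0.40 with an estimated correlation) to -0.06 (adjusted p = 0.021 with an estimated correlation), where TGFBI was the 1 member that fell over all genes. None of these lists had a member past the threshold in the 18 arrays, over all genes or adjusted over the list alone. The remaining lists are given by their median against the beads in the 18 arrays and, after it, in the 16. Antigen presentation was at 0.37 and -0.11, NF-kB-driven endothelial activation at 0.06 and -0.07, angiogenesis and Notch genes at 0.31 and -0.09, and the G1/S and DNA replication genes at -0.06 and -0.17. The unfolded protein response was at 0.34 and -0.02, hypoxia and glycolysis genes at 0.38 and -0.01, p53 targets at 0.37 and -0.06, and oxidative stress and metallothionein genes at 0.78 and 0.09. The CD47 and thrombospondin axis was at 0.28 and 0.01, the tetraspanins and vesicle biogenesis genes at 0.66 and 0.00, and the respiratory chain at 0.40 and 0.09. Markers of other cell types were at -0.34 and 0.05 for fibroblasts and smooth muscle, -0.26 and 0.08 for monocytes, and -0.35 and 0.03 for epithelium. The replication-dependent histones were at 0.01 and 0.05, the small nucleolar and spliceosomal RNAs at 0.22 and 0.18, and the microRNA precursors at -0.21 and 0.05. For hypoxia the median and the mean differed in sign in the 16 arrays (mean 0.01), as they did for the tetraspanins (median 0.004, mean -0.005). Of these lists, 1 member of the NF-kB list fell in the 18 arrays and 1 small nucleolar RNA rose when adjusted over the list alone. In the 18 arrays camera with its preset correlation called 13 lists up and 6 down, and none of these calls held with an estimated correlation.

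**Figure D4:**
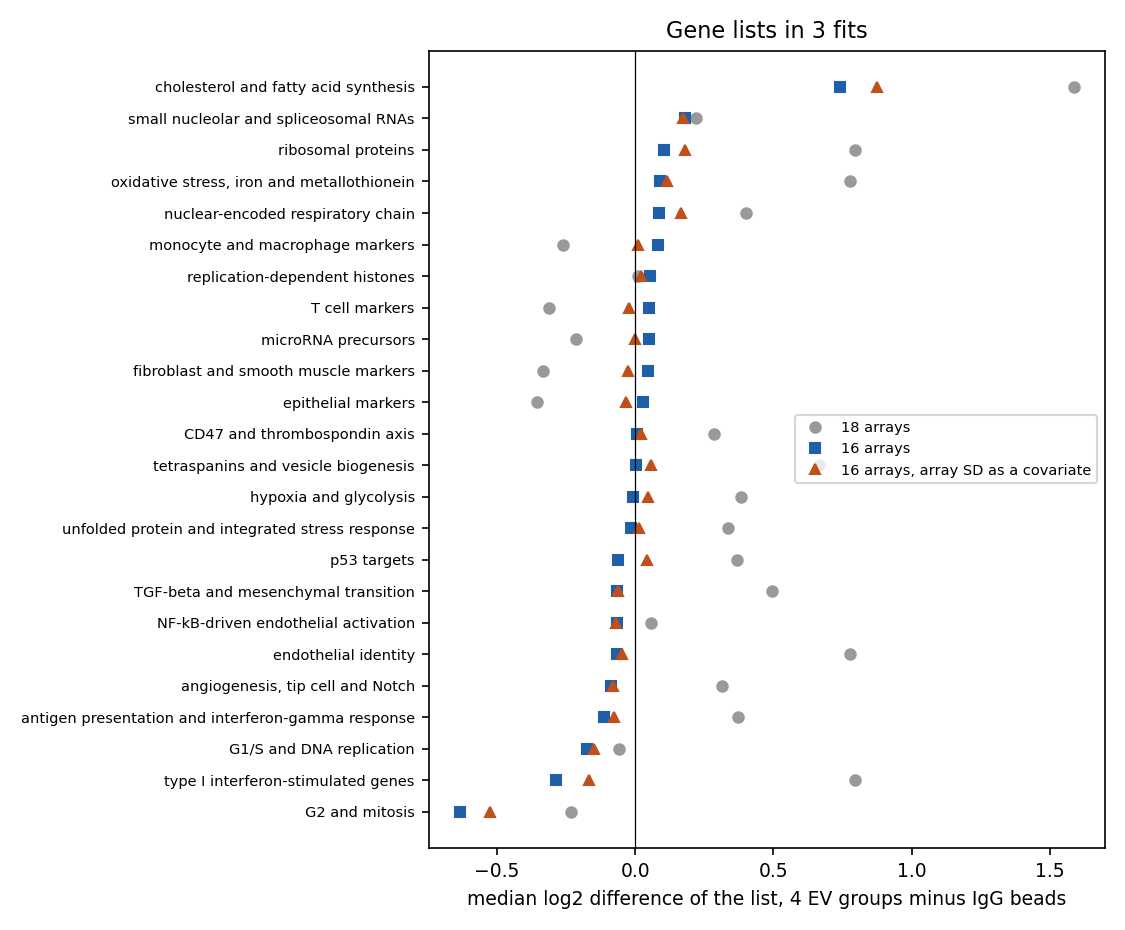
Median log2 difference of each of the 24 gene lists between the mean of the 4 EV groups and the IgG beads, in the 18 arrays (grey circles), the 16 arrays (blue squares) and the 16 arrays with the array SD as a covariate (red triangles). The cholesterol and fatty acid list is at 1.59, 0.74 and 0.87 and the G2 and mitosis list at -0.23, -0.63 and -0.53, while most other lists lie near 0 in both fits on 16 arrays.

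Each EV group was also set against the beads alone, and these 4 comparisons share the same bead arrays. With Jurkat CD63+ EVs, STC1 rose by 1.51 ± 0.18 (3 arrays against 3; limma adjusted p = 0.0088) and was the 1 gene called. The count fell to 0 without bead replicate 1 or 2, without any 1 of the 3 Jurkat CD63+ arrays, with trend and robust options, after quantile normalization again, and with only the groups compared. FASN was at 1.52 ± 0.37 (adjusted p = 0.60) and INSIG1 at 1.90 ± 0.50 (adjusted p = 0.60). The cholesterol and fatty acid list had a median of 1.63 with 13 members up adjusted over the list alone and 0 over all genes (adjusted p = 0.42 with an estimated correlation). In the 16 arrays STC1 was again the 1 gene called, at 1.63 ± 0.14 (adjusted p = 0.00015), and the list had a median of 0.78 with 19 members up adjusted over the list alone (adjusted p = 0.0094 with an estimated correlation). Without the doubted Jurkat MHC1+ array as well, in 15 arrays, 7 genes rose and 1 fell.

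With Jurkat MHC1+ EVs limma called 0 genes in the 18 arrays, with 219 at an unadjusted p under 0.05, and 0 in the 16 and the 15 arrays. FASN was at 1.58 ± 0.37 (adjusted p = 0.98), VCAM1, a leukocyte adhesion molecule, at -0.63 ± 0.18 (adjusted p = 0.98) and STC1 at 0.56 ± 0.18 (adjusted p = 0.98). The G2 and mitosis list had a median of -0.38 (camera adjusted p = 4.7e-07; adjusted p = 0.52 with an estimated correlation) and the cholesterol list of 1.04 (camera adjusted p = 1.4e-15; adjusted p = 0.38 with an estimated correlation). In the 16 arrays 25 of the 30 mitosis genes fell adjusted over the list alone and 0 over all genes (median -0.83; adjusted p = 0.21 with an estimated correlation). The cholesterol list had a median of 0.36 there (adjusted p = 0.53 with an estimated correlation). This group holds the array of intermediate quality, replicate 1. In the 15 arrays, without it, both lists were called with an estimated correlation. The median was 0.70 for cholesterol (adjusted p = 0.011) and -0.68 for mitosis (adjusted p = 0.028). Both were called with the array SD as a covariate too, at 0.64 (adjusted p = 0.0027) and -0.62 (adjusted p = 0.011).

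With JinB8 CD63+ EVs, STC1 rose by 2.06 ± 0.18 (3 arrays against 3; limma adjusted p = 0.00017), the 1 gene called in the 18 arrays; after quantile normalization again, and with only the groups compared, 0 genes were called. With 16 arrays 5 genes rose and 12 fell. FASN rose by 1.31 ± 0.16 (adjusted p = 0.0055) and INSIG1 by 1.51 ± 0.25 (adjusted p = 0.033) there. TGFB2, a growth factor of the TGF-beta family, fell by 1.32 ± 0.19 (adjusted p = 0.018), P3H2, a collagen-modifying hydroxylase, by 1.31 ± 0.20 (adjusted p = 0.022), TGFBI by 1.04 ± 0.11 (adjusted p = 0.0016) and COL12A1, a collagen chain, by 0.98 ± 0.17 (adjusted p = 0.047). ASPM fell by 1.26 ± 0.21 (adjusted p = 0.037) and MKI67 by 1.10 ± 0.19 (adjusted p = 0.042). None of these 6 falls passed in the 18 arrays, where TGFB2 was at -0.03 ± 0.98, P3H2 at -1.13, TGFBI at -0.58, COL12A1 at -0.61, ASPM at -0.60 and MKI67 at -0.81. Leaving out bead replicate 2 gave a rise of 0.63 for TGFB2, and leaving out bead replicate 1 one of 0.59. Its direction thus rests on leaving out bead replicate 3. The other 5 stayed negative with each array left out in turn. In the 18 arrays the cholesterol list had 17 members up adjusted over the list alone and 0 over all genes (median 1.81; adjusted p = 0.11 with an estimated correlation), and in the 16 arrays 20 and 4 (median 0.90; adjusted p = 0.036 with an estimated correlation). With 15 arrays 18 genes rose and 36 fell.

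With JinB8 MHC1+ EVs, the RNAs that rose were short and non-coding. All 8 genes past the threshold in the 18 arrays were of this kind: the small nucleolar RNAs SNORA62, SNORD38B, SNORA65, SNORA38B, SNORD104, SNORA68 and SNORD38A, which guide chemical modification of ribosomal and other RNAs, and VTRNA1-1, an RNA of the vault particle. Of the arrays left out in turn, JinB8 MHC1+ replicate 1 or 2 left 1 gene called, JinB8 MHC1+ replicate 3 left 5 and bead replicate 2 left 2. Quantile normalization again gave 3, and a fit of only the groups compared gave 0. SNORA38B rose by 2.36 ± 0.20 (3 arrays against 3; limma adjusted p = 0.00017), from 6.26 ± 0.30 (SD, n = 3) with beads to 8.62 ± 0.09. The changes of the 8 ranged from 1.32 for SNORD38A to 2.80 ± 0.44 for SNORA62 (adjusted p = 0.036), and VTRNA1-1 rose by 2.26 ± 0.33 (adjusted p = 0.017). The list of small nucleolar and spliceosomal RNAs (203 measured) had a median of 0.73, with 7 members up over all genes and 67 adjusted over the list alone, and its call held with an estimated correlation (adjusted p = 0.0045). With 16 arrays 36 genes rose and 3 fell, and 27 of this list rose over all genes and 89 adjusted over the list alone (median 0.53; adjusted p = 0.0027 with an estimated correlation). STC1 at 1.08 ± 0.14 (adjusted p = 0.0046) and INSIG1 at 1.63 ± 0.25 (adjusted p = 0.01) were among those that rose in the 16 arrays, and the 3 that fell were ASPM by 1.32 ± 0.21 (adjusted p = 0.015), MKI67 by 1.15 ± 0.19 (adjusted p = 0.018) and BUB1B by 1.07 ± 0.18 (adjusted p = 0.02). In the 18 arrays these 3 were at -0.66, -0.86 and -0.72, none past the threshold. Without bead replicate 1 they were at -0.28, -0.65 and -0.47. With 15 arrays 93 genes rose and 23 fell. Closely related copies exist within these RNA families, and their probe sets were not compared for shared probe sequence.

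The bead control was compared with untreated cells to see what the beads do on their own. Limma called 0 genes, with 203 at an unadjusted p under 0.05, and 0 in the 16 and 15 arrays. The smallest p-values belonged to MIEN1, a membrane-anchored migration protein, at -0.69 ± 0.18 (adjusted p = 1.00), NDUFB11, a subunit of respiratory complex I, at -0.80 ± 0.21 (adjusted p = 1.00), and SNORA74A, a small nucleolar RNA, at 0.99 ± 0.27 (adjusted p = 1.00). The replication-dependent histones had a median of -0.18 (camera adjusted p = 0.00047; adjusted p = 1.00 with an estimated correlation). The endothelial identity list was at -0.30 (camera adjusted p = 0.034; adjusted p = 1.00 with an estimated correlation) and at 0.01 in the 16 arrays. Each of these 2 groups holds 1 discordant array, which widens the spread against which every gene was tested.

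The comparisons of JinB8 with Jurkat EVs ask what the loss of CD47 on the donor cell changes. Any other difference between the JinB8 and Jurkat lines cannot be told apart from CD47 here. Conditioned media were pooled for each donor cell, so the arrays of a group do not replicate the donor cell culture. With MHC1 capture, 6 short RNAs rose in the 18 arrays and none fell: SNORA38B by 2.10 ± 0.20 (3 arrays against 3; limma adjusted p = 0.00081), SNORD38B by 2.43 ± 0.36 (adjusted p = 0.041), VTRNA1-1 by 2.26 ± 0.33 (adjusted p = 0.041), SNORA65 by 2.21 ± 0.35 (adjusted p = 0.049), SNORD104 by 1.49 and SNORD38A by 1.34. The small nucleolar and spliceosomal RNA list had a median of 0.59 with 168 of 203 members positive, 5 up over all genes and 71 adjusted over the list alone, and its call held with an estimated correlation (adjusted p = 0.00019). With 16 arrays 70 genes rose and 1 fell, 54 of the list rose over all genes and 107 adjusted over the list alone, and the list's call was lost with an estimated correlation (adjusted p = 0.06). Protein-coding genes that rose in the 16 arrays included CCL20, a chemokine, by 1.80 ± 0.31 (adjusted p = 0.019), TXN, the redox protein thioredoxin, by 1.56 ± 0.27 (adjusted p = 0.02), and SDHD, a subunit of respiratory complex II, by 1.17 ± 0.22 (adjusted p = 0.03). With the array SD as a covariate 39 genes rose, and CCL20 was at 1.14 (adjusted p = 0.062), TXN at 0.95 (adjusted p = 0.059) and SDHD at 0.79 (adjusted p = 0.21). The genes at an unadjusted limma p under 0.05 numbered 5438 in the 16 arrays and 1192 with the covariate. Leaving out any 1 of the 6 arrays compared left 1 to 2 genes past the threshold in the remaining 17, and quantile normalization again gave 0.

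In the same comparison, camera's preset test called 10 lists up and 4 down, and of these the small nucleolar list alone was called with an estimated correlation. The respiratory chain had a median of 0.54 (camera adjusted p = 3.0e-16; adjusted p = 0.41 with an estimated correlation), the ribosomal proteins of 0.52 (camera adjusted p = 1.2e-08; adjusted p = 0.63 with an estimated correlation), the cholesterol list of 0.58 (camera adjusted p = 4.5e-05; adjusted p = 0.63 with an estimated correlation) and the interferon-stimulated genes of 0.40 (camera adjusted p = 0.0027; adjusted p = 0.74 with an estimated correlation). The 4 lists that were lower have low mean levels: the epithelial markers had a median of -0.23, the T cell markers of -0.20, the microRNA precursors of -0.18 and the monocyte markers of -0.17 (adjusted p = 0.74 with an estimated correlation for each). None of these 8 lists had a member past the threshold over all genes or adjusted over the list alone in the 18 arrays. With the array SD as a covariate the medians were 0.28 for the respiratory chain, 0.29 for the ribosomal proteins, 0.20 for the cholesterol list and 0.08 for the interferon-stimulated genes. Camera's preset test did not call the 4 lower lists in that fit. The SDs over all probe sets were 2.21 to 2.25 on the JinB8 MHC1+ arrays and 2.01 to 2.21 on the Jurkat MHC1+ arrays.

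With CD63 capture, JinB8 and Jurkat EVs differed in 0 genes by limma, with 47 at an unadjusted p under 0.05 in the 18 arrays and 740 in the 16. Both counts are below the share of 0.05 that genes without a difference would give. The spread in the 18 arrays includes that of the 2 discordant controls, which are not compared here. The median SE was 0.34 in the 18 arrays and 0.16 in the 16. Other comparisons between EV groups share this widened spread, so low counts there do not show that differences are absent. STC1 was at 0.55 ± 0.18 (adjusted p = 1.00), and SPAG5, a spindle protein, at -0.80 ± 0.33 (adjusted p = 1.00). The G2 and mitosis list had a median of -0.49 with 1 of 30 members positive (camera adjusted p = 1.3e-17; adjusted p = 0.32 with an estimated correlation), and the G1/S and DNA replication list of -0.24 (camera adjusted p = 2.4e-11; adjusted p = 0.14 with an estimated correlation). In neither list did a member pass over all genes or adjusted over the list alone in the 18 arrays. Averaged over both captures, limma called 0 genes in the 18 arrays (130 at an unadjusted p under 0.05) and 10 up in the 16, all of them small nucleolar RNAs; SNORA38B was at 1.04 ± 0.14 (adjusted p = 0.063) in the 18 arrays and at the same value with an SE of 0.11 in the 16 (adjusted p = 0.003). The small nucleolar and spliceosomal list had a median of 0.33 with 9 members up adjusted over the list alone and 0 over all genes (adjusted p = 2.7e-05 with an estimated correlation). This average comes mostly from MHC1 capture. With CD63 capture the list's median was 0.03 (adjusted p = 0.92 with an estimated correlation). Its mean level was 5.53 with JinB8 and 5.51 with Jurkat EVs, against 6.05 and 5.36 with MHC1 capture. Comparing the list means of the 6 JinB8 and 6 Jurkat EV arrays gave exact permutation p = 0.037 (two-sided; adjusted p = 0.29). The endothelial identity list differed most clearly in that comparison, by -0.09 (exact permutation p = 0.0022, two-sided; adjusted p = 0.052). Its mean lay at 8.32 to 8.39 on the JinB8 EV arrays and 8.40 to 8.46 on the Jurkat EV arrays. CD47 itself, the gene missing in the donor cells, was measured here in endothelial cells, where its difference was 0.40 ± 0.50 (adjusted p = 1.00). THBS1, the CD47 ligand thrombospondin 1, was at -0.10 ± 0.66 (adjusted p = 1.00) and NOS3, the endothelial nitric oxide synthase, at -0.10 ± 0.12 (adjusted p = 1.00).

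The comparison of CD63+ with MHC1+ EVs asks whether the vesicle subsets act differently. Averaged over both donor cells, STC1 was higher with CD63+ EVs by 1.03 ± 0.13 (6 arrays against 6; limma adjusted p = 0.007), and SNORA38B was at -1.30 ± 0.14 (adjusted p = 0.0045); these 2 were the genes called, with 74 at an unadjusted p under 0.05. The count was 1 with trend and robust options and 0 after quantile normalization again. Among 16 arrays 1 gene was higher and 3 were lower, among them TGFBI at -0.49 ± 0.07 (adjusted p = 0.032) and SNORD42A at -0.58 ± 0.09 (adjusted p = 0.032). With the array SD as a covariate the balance turned, with 560 genes higher and 179 lower. The small nucleolar list had a median of -0.16 with 1 member down over all genes and 3 adjusted over the list alone (adjusted p = 0.0016 with an estimated correlation), a call lost in the 16 arrays (0.072), the 15 arrays (0.089) and with the covariate (0.36), where the median was -0.16, -0.22 and -0.13. The NF-kB-driven endothelial activation list, which holds adhesion molecules and chemokines, had a median of -0.09 and a mean of -0.13 (adjusted p = 0.039 with an estimated correlation), with 20 of its 30 members negative and 0 past the threshold over all genes or adjusted over the list alone. With an estimated correlation the NF-kB call held in the 16 arrays (adjusted p = 0.032) and was lost in the 15 arrays (0.14) and with the covariate (0.36). Exact permutation of the 12 EV arrays gave p = 0.063 (adjusted p = 0.75). In the same permutation test the TGF-beta and mesenchymal transition list had the smallest p, with a mean lower by 0.09 (p = 0.0022, adjusted p = 0.052). It lay at 7.77 to 7.88 on the CD63+ arrays and 7.89 to 7.97 on the MHC1+ arrays, and camera did not call it in the 18 arrays (adjusted p = 0.16; adjusted p = 0.79 with an estimated correlation). The interferon-stimulated genes were at -0.23 (camera adjusted p = 2.1e-05; adjusted p = 0.67 with an estimated correlation). CD63, the capture antigen's own gene in the recipient cells, was at -0.09 ± 0.50 (adjusted p = 1.00).

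Within Jurkat EVs, limma called 0 genes between the captures in the 18 arrays (81 at an unadjusted p under 0.05), and STC1 was at 0.96 ± 0.18 (adjusted p = 1.00); in the 16 arrays it was the 1 gene called (SE 0.13, adjusted p = 0.033). The G2 and mitosis list had a median of 0.46 (camera adjusted p = 8.8e-11; adjusted p = 0.58 with an estimated correlation), and 0 of its members passed in either way. Within JinB8 EVs, SNORA38B was lower with CD63 capture, at -2.35 ± 0.20 (3 arrays against 3; limma adjusted p = 0.00018), and was the 1 gene called, with 314 at an unadjusted p under 0.05. STC1 was at 1.10 ± 0.18 (adjusted p = 0.086) and SNORD37, another small nucleolar RNA, at -1.40 ± 0.23 (adjusted p = 0.11). The small nucleolar list had a median of -0.46 with 1 member down over all genes and 45 adjusted over the list alone (adjusted p = 0.00035 with an estimated correlation). Among 16 arrays 2 genes were higher and 32 lower with CD63 capture, among them STC1 (adjusted p = 0.0018), and CCL2, a monocyte chemokine, at -0.88 ± 0.14 (adjusted p = 0.019). The small nucleolar list's call did not hold with an estimated correlation in the 16 arrays (adjusted p = 0.10). The median of the list was the same there, because only controls were left out. With 15 arrays 71 genes were higher and 284 lower.

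The interaction tests whether the difference between JinB8 and Jurkat EVs depends on the capture. Limma called 0 genes in the 18 arrays, with 450 at an unadjusted p under 0.05. SNORA38B had the smallest p, at -2.11 ± 0.29 (adjusted p = 0.054), and VTRNA1-1 was at -2.37 ± 0.46 (adjusted p = 0.92). In the 16 arrays 3 small nucleolar RNAs passed: SNORA38B (adjusted p = 0.0025), SNORD42A at -1.39 ± 0.17 (adjusted p = 0.0078) and SNORA37 at -1.64 ± 0.22 (adjusted p = 0.013). An unadjusted limma p under 0.05 was reached by 5289 of the 18395 genes there, by 3324 in the 15 arrays and by 633 with the array SD as a covariate. The broad shift in the 16 arrays was thus largely not kept with the covariate. The small nucleolar and spliceosomal list had a median of -0.50 with 28 members down adjusted over the list alone and 0 over all genes (adjusted p = 0.0032 with an estimated correlation; 0.37 in the 16 arrays, 0.21 in the 15 and 0.062 with the covariate, where the median was -0.50, -0.45 and -0.47). Its mean was higher on the 3 JinB8 MHC1+ arrays than on the 9 other EV arrays by 0.59 (exact permutation p = 0.0045, the smallest that 220 splits can give, two-sided; adjusted p = 0.036 over the 24 lists). This group was set apart after its values had been seen, and the adjustment does not cover that choice. The permutation compares 1 group with the others and does not test the interaction itself. The shift was not particular to this list. On these 3 arrays 8 other lists were higher as well. Among them were the respiratory chain by 0.43 and NF-kB by 0.24 (exact permutation p = 0.0045 for each), and the interferon-stimulated genes by 0.43, the ribosomal proteins by 0.42 and the oxidative stress genes by 0.32, all 5 at an adjusted p of 0.036. The last 3 were antigen presentation by 0.31, the unfolded protein response by 0.22 and the histones by 0.16 at an adjusted p of 0.048. Lists of low level were lower on these arrays, the epithelial markers by 0.18 and the microRNA precursors by 0.14 (adjusted p = 0.094 for each) and the T cell markers by 0.15 (adjusted p = 0.16). The endothelial identity list, which has a high level, was lower too, by 0.07 (exact permutation adjusted p = 0.060). The SDs over all probe sets of these 3 arrays, 2.21 to 2.25, were among the highest. The test for any difference among the 6 groups called 2 genes in the 18 arrays, 43 in the 16 and 122 in the 15.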

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

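The 15 gene lists below differed between the captures in the interaction of donor cell and capture, by camera with its preset correlation in the 18 arrays; the tests of explanations given here were chosen only after the result was seen, except that of the host genes. A negative value means that the difference between JinB8 and Jurkat EVs was lower with CD63 than with MHC1 capture. The small nucleolar and spliceosomal RNAs had a median interaction of -0.50, and this list was the 1 called with an estimated correlation as well (adjusted p = 0.0032), a call that was lost in the 16 arrays (adjusted p = 0.37), in the 15 arrays (0.21) and with the array SD as a covariate (0.062). The size of the difference hardly moved, with medians of -0.50, -0.45 and -0.47 in these fits, while the correlation estimated within the list rose from 0.048 to 0.11, 0.10 and 0.14. The 16 arrays leave out only controls, which do not enter this difference, so its size could not change there. These controls do enter the spread from which the correlation was estimated. The call in the 18 arrays therefore depended on arrays outside this difference, and it was lost in each of these fits without the discordant controls. The loss thus weakens the call, though not the size of the difference. The ribosomal proteins were at -0.68, the respiratory chain at -0.66, the G2 and mitosis genes at -0.56, the interferon-stimulated genes at -0.50, antigen presentation at -0.48, hypoxia and glycolysis at -0.46, the cholesterol and fatty acid genes at -0.45, the oxidative stress genes at -0.39, the G1/S genes at -0.33, the unfolded protein response at -0.28 and the histones at -0.27. The T cell markers were at 0.31, the monocyte markers at 0.33 and the microRNA precursors at 0.21. With an estimated correlation the adjusted p of these other lists lay between 0.39 and 0.72. With the array SD as a covariate in the 16 arrays the interferon list was at 0.02, the cholesterol list at 0.18 and the T cell markers at -0.07, so that array quality may carry part of these interactions.

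The small nucleolar and spliceosomal RNAs were higher with JinB8 MHC1+ than with Jurkat MHC1+ EVs by a median of 0.59. A difference in array quality as the whole cause is argued against by the fit with the array SD as a covariate, where the median stayed at 0.53 and the list was called with an estimated correlation (adjusted p = 0.009), as it was in the 18 arrays (0.00019) and the 15 arrays (0.014) but not in the 16 arrays without the covariate (0.06), where the median was the same as in the 18. A larger content of short RNA in these RNA samples may be part of the cause: the 7 short RNAs outside the list had a median difference of 0.82, from 2.26 for VTRNA1-1 to -0.36 for TERC. VTRNA1-1 had already been called in this comparison. VTRNA1-2 was at 1.33, VTRNA1-3 at 0.87, RMRP at 0.82, RNY1 at 0.44 and RPPH1 at 0.20 (limma adjusted p = 0.0059, 0.073, 0.010, 0.29 and 0.67, 16 arrays). With the array SD as a covariate all 7 were positive, from 2.13 for VTRNA1-1 to 0.10 for TERC, with RPPH1 at 0.78. The microRNA precursors had a mean level of 4.02 with JinB8 and 4.20 with Jurkat MHC1+ EVs. These levels are near 4.17, below which the lowest 25% of genes lie, so they say little. A rise of every kind of short RNA is thus neither shown nor excluded. Transcription of the host genes was not decided, since the 17 host genes had a median of 0.43 with quartiles of 0.21 and 0.60 against 1.17 for the 26 RNAs in their introns. Donor cell CD47, RNA extraction and array order are open and were not tested. The sample labels and the series design name different RNA kits, which can differ in how much short RNA they keep, so it is not known how fully these RNAs were retained.

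The cholesterol and fatty acid synthesis genes were higher in the 4 EV groups than with beads. The discordant control arrays as the whole cause are argued against by the fit without them, where the median against the beads was 0.74 and the list was called with an estimated correlation (adjusted p = 0.017). Exact permutation without them gave p = 0.0022 against the 4 control arrays pooled, and 0.033 (adjusted p = 0.26 over the 24 lists) against the 2 bead arrays alone. Array quality is argued against by the median of 0.87 with the array SD as a covariate, and unusually low bead controls by the median of 0.81 against untreated cells. The labels give no time in culture for the untreated cells. A difference in that time is thus not covered by the comparison with them or by the pooled permutation. An effect of the vesicles on sterol-regulated transcription is a hypothesis that no test here decides. Culture density, medium carried over with the captured vesicles, and array order were not tested and stay open.

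The G2 and mitosis genes were lower in the 4 EV groups than with beads. The discordant control arrays are argued against by the fit without them, where the median against the beads was -0.63 and the list was called with an estimated correlation (adjusted p = 0.017). Exact permutation without them gave p = 0.0011 against the 4 control arrays pooled, and 0.022 (adjusted p = 0.26 over the 24 lists) against the 2 bead arrays alone. Also argued against are array quality by the median of -0.53 with the array SD as a covariate, and unusually high bead controls by the median of -0.59 against untreated cells. The labels give no time in culture for the untreated cells. A difference in that time is thus not covered by the comparison with them or by the pooled permutation. Slower division of cells kept with vesicles is a hypothesis that no test here decides, and a difference in culture density stays open, since cell numbers were not analysed here. In the 18 arrays the median was 0.08 without bead replicate 1. The bead group then held replicate 2, with a list mean of 6.15, and the discordant replicate 3, with 5.14. The change of direction thus depends on replicate 3 as well.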

How the results depend on the processing

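The 228 results were recomputed under 16 alternative settings, besides leaving out each array in turn. Of 2134 values, 1425 kept their direction and side of the threshold (counts: stayed within 1.5 times), 228 were weaker, 356 stronger, 66 counts moved and 59 values reversed; 58 of the reversals came from settings chosen after seeing the data. These settings are the fits on 16 and 15 arrays, the array SD as a covariate, and untreated cells as the control for lists. No paired analysis was possible because the labels give no replicate numbers shared across groups. The default array weights did not converge, so the gene-by-gene method was used. Where arrays or genes were left out, the number tested changed by construction; otherwise the cause was not tested. Genes near background limit what can be seen, and no detection call was used.

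With limma's trend and robust options the counts were 0 for Jurkat CD63+ EVs and for the mean of the EV groups against beads, and 1 for CD63+ against MHC1+ EVs. With arrays quantile-normalized again they were 3 for JinB8 MHC1+ EVs against beads and 0 for Jurkat CD63+, JinB8 CD63+ and the mean of the EV groups against beads, for JinB8 against Jurkat MHC1+ EVs, for the averaged captures and for the F test. With arrays centred on their medians, JinB8 against Jurkat EVs averaged and the interaction each gave 1. Leaving out the lowest 50% of genes gave 5 for JinB8 MHC1+ EVs against beads and 1 for JinB8 against Jurkat MHC1+ EVs. With only the groups compared, the 3 comparisons of Jurkat CD63+, JinB8 CD63+ and JinB8 MHC1+ EVs with beads gave 0, JinB8 against Jurkat MHC1+ EVs 14, JinB8 against Jurkat averaged 4, CD63+ against MHC1+ within JinB8 56, and the interaction 4. Array weights gave 22 for Jurkat CD63+ EVs minus IgG beads, 80 for Jurkat MHC1+ EVs minus IgG beads, 74 for JinB8 CD63+ EVs minus IgG beads, 1214 for JinB8 MHC1+ EVs minus IgG beads, 88 for mean of the 4 EV groups minus IgG beads, 6145 for JinB8 MHC1+ EVs minus Jurkat MHC1+ EVs, 74 for JinB8 EVs minus Jurkat EVs, averaged over capture, 157 for Jurkat CD63+ EVs minus Jurkat MHC1+ EVs, 3532 for JinB8 CD63+ EVs minus JinB8 MHC1+ EVs, 149 for CD63+ EVs minus MHC1+ EVs, averaged over donor cell, 5137 for interaction of donor cell and capture and 5185 for any difference among the 6 groups. Of these, 302 of the 1214 and 2760 of the 6145 were lower.

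In 16, 15 and 16 arrays with the SD as a covariate, the counts were 17, 54 and 80 for JinB8 CD63+ EVs against beads, 39, 116 and 198 for JinB8 MHC1+ EVs, 8, 28 and 52 for the mean, 71, 58 and 39 for JinB8 against Jurkat MHC1+, 10, 16 and 49 averaged, 1, 1 and 1 for the captures within Jurkat, 34, 355 and 24 within JinB8, 4, 13 and 739 averaged, 3, 15 and 2 for the interaction, and 43, 122 and 312 for the F test. Jurkat CD63+ EVs against beads gave 8 in 15 arrays and 22 with the covariate, and Jurkat MHC1+ EVs 8 with the covariate. Beads against untreated cells and JinB8 against Jurkat CD63+ EVs gave 0 in every setting run. With each array left out in turn, counts ranged from 1 to 8 for JinB8 MHC1+ EVs against beads, 1 to 2 for JinB8 against Jurkat MHC1+ EVs and for the captures within JinB8, 0 to 1 for Jurkat CD63+ EVs and the mean against beads, JinB8 against Jurkat averaged and the interaction, and 2 to 6 for the F test. The mean of the EV groups gave 0 without bead replicate 1 or 2, and JinB8 MHC1+ EVs against beads gave 1 without its replicate 1 or 2, 5 without its replicate 3 and 2 without bead replicate 2.

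Lists that reversed against beads did so mostly in settings without bead replicate 3. In 16 arrays, in 15 arrays and with untreated controls in 16, the medians were -0.29, -0.23 and -0.32 for interferon-stimulated genes, -0.11, -0.097 and -0.18 for antigen presentation, -0.065, -0.076 and -0.078 for NF-kB, -0.068, -0.038 and -0.060 for endothelial identity, -0.064, -0.043 and -0.049 for TGF-beta, -0.017, -0.0021 and -0.034 for the unfolded protein response, 0.084, 0.050 and 0.032 for monocyte markers, 0.049, 0.026 and 0.019 for microRNA precursors, and 0.047, 0.0080 and -0.0016 for fibroblast markers. They were -0.087 and -0.077 in 16 and 15 arrays for angiogenesis, -0.064 and -0.011 for p53 targets and 0.051 and 0.015 for T cell markers, and 0.028 in 16 arrays for epithelial markers. With the SD as a covariate they were -0.17 for interferon, -0.069 for NF-kB, -0.047 for endothelial identity, -0.062 for TGF-beta, -0.080 for angiogenesis, 0.012 for the unfolded protein response and 0.011 for monocyte markers. Untreated controls in 16 arrays gave -0.024 for ribosomal proteins, -0.047 for the respiratory chain, 0.021 for oxidative stress, -0.027 for epithelial markers and -0.062 for histones (-0.12 in 18). Without bead replicate 3 the medians against beads equal those in 16 arrays. With each array left out in turn the medians ranged from -0.29 to 1.33 for interferon, -0.11 to 0.71 for antigen presentation, -0.065 to 0.15 for NF-kB, -0.087 to 0.56 for angiogenesis, -0.064 to 0.88 for TGF-beta, -0.017 to 0.56 for the unfolded protein response, -0.064 to 0.64 for p53 targets, -0.54 to 0.051 for T cell, -0.48 to 0.047 for fibroblast and -0.44 to 0.084 for monocyte markers, and -0.36 to 0.049 for microRNA precursors.

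Endothelial identity between beads and untreated cells was at 0.011 in 16 and 15 arrays and ranged from -0.67 to 0.67 with each array left out in turn. The G2 and mitosis list with Jurkat CD63+ EVs was at -0.33 in 16 and 15 arrays, -0.27 with the covariate and 0.12 without the lowest 50% of genes, and ranged from -0.33 to 0.37 with each array left out. With JinB8 MHC1+ EVs, where the direction of the test changed without bead replicate 1, it ranged from -0.65 to -0.0044 and for the mean from -0.63 to 0.076, the highest being that without bead replicate 1. For the interaction the covariate gave 0.021 for interferon, 0.061 for antigen presentation, 0.18 for cholesterol, 0.016 for the unfolded protein response, -0.072 for T cell markers and -0.053 for microRNA precursors.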

Other observations

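CCL2, a monocyte chemokine, stood at 10.84 ± 0.24 (SD, n = 3) with JinB8 CD63+ EVs and 11.72 ± 0.06 with JinB8 MHC1+ EVs, against 11.37 with beads (n = 2) in the 16 arrays. TXN, the redox protein thioredoxin, was at 10.84 ± 0.13 with JinB8 MHC1+ EVs and 9.29 ± 0.76 with Jurkat MHC1+ EVs. KDR, the main VEGF receptor, lay between 9.80 and 10.09 in all groups of the 16 arrays. Transcripts that mark T cells stayed at a low level with EVs: CD3E was between 3.56 and 3.77 and PTPRC between 3.04 and 3.19 in the EV groups, and 3.59 and 2.96 with beads.

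The following tests compared each real grouping with other groupings of the same arrays and were chosen only after the result was seen. For the mean of the 4 EV groups against beads, 1 gene was called and at most 0 in the other splits of 100, and for CD63+ against MHC1+ EVs averaged, 2 genes were called and at most 1 otherwise. In both, 1 of 100 splits, the real one, gave as many, by a margin of 1 gene. A margin this small, in tests chosen after the result, does not exclude chance. For the mean of the EV groups, the other splits also moved the discordant bead replicate 3 between groups, so they are not fully comparable with the real one. The first count fell to 0 without bead replicate 1 or 2, with trend and robust options and after quantile normalization again; the second fell to 1 with trend and robust options and to 0 after quantile normalization again. For JinB8 against Jurkat EVs averaged, 0 genes were called and up to 4 in other splits, and for the interaction 0 and up to 1, but with a count of 0 all 100 splits give as many whatever the data, so these 2 tests say nothing about chance. The F test called 2 genes, and 4 of 100 splits gave as many. The highest of these, 12627 genes, came from a split that put the 2 discordant controls into one group with Jurkat MHC1+ replicate 1, the array of intermediate quality, which points to the structure of these arrays.

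With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts were 8 and 0 for JinB8 MHC1+ EVs against beads, 6 and 0 for JinB8 against Jurkat MHC1+ EVs, and 1 and 0 for Jurkat CD63+ and JinB8 CD63+ EVs against beads and for the captures within JinB8. They were 0 and 0 for Jurkat MHC1+ EVs against beads, JinB8 against Jurkat CD63+ EVs and the captures within Jurkat. For beads against untreated cells they were 0 and 12451, where the split put the 2 discordant arrays into the same group.

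The 12083 probe sets without an annotated gene were tested separately. For the mean of the 4 EV groups against beads, limma called 0 up and 1 down in the 18 arrays, with 896 at an unadjusted p under 0.05, and 2 up and 0 down in the 16 arrays. In the 16 arrays JinB8 against Jurkat MHC1+ EVs gave 2 up and 1 down. The CD63+ against MHC1+ captures within JinB8 gave 3 up and 2 down there. No other comparison called any of these probe sets in the 18 or the 16 arrays.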
